A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

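The series holds 4 two-colour arrays of Cdc45-13Myc ChIP-chip from W303 yeast in G1, 2 from CDC7 and 2 from cdc7-4 cells. Per the labels, the IP was labelled with Cy3 (green) and 5 µg of input DNA with Cy5 (red) on every array, 50 ml of culture went into each sample, and no dye swap was made, so a dye effect does not cancel within a genotype. Groups and replicate numbers were taken from the labels. All 4 arrays lie on 1 slide, the cdc7-4 arrays at positions 1 and 2 and the CDC7 arrays at positions 3 and 4, so position and genotype coincide.

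Per the file headers, Agilent Feature Extraction 10.1.1.1 with its ChIP protocol read the scans, and the deposited intensity values include spot means, local background medians, background-subtracted signals and processed signals, the last background-subtracted, detrended and dye-normalized within the array. The deposited log10 ratio of red over green equalled that of the processed signals within 0.001 for at least 99.85% of spots. The authors' value table holds log2 ratios whose centring and method are not given in the sources used here. Its rows follow the spot order of the array (r = 0.851 to 0.892 with log2 of IP over input, about 0 by feature number), its direction is IP over input, its slope on the processed ratio is 0.732 to 0.803, and its column medians over all rows are -0.0049, -0.0046, -0.0026 and -0.0050 for CDC7 arrays 1 and 2 and cdc7-4 arrays 1 and 2. The genome build of the probe coordinates is not given in the sources used here.

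The 2543 control spots were left out. The ratio of processed signals, IP over input, was taken as log2 and centred on the median of each array, with spots called outliers by the scanner software left out and no loess or quantile step. Median background-subtracted signals were 1388.8 and 1651.0 (IP) and 34462 and 32073 (input) for the CDC7 arrays, and 2050.1 and 1689.5 (IP) and 26437.6 and 30949.6 (input) for the cdc7-4 arrays. No spot was saturated, and cdc7-4 array 1 had 397 IP and 1017 input spots called non-uniform, against at most 33 on any other array. The number of arrays limits the precision of every value. Replicate arrays held no identical values at any probe and differed by a median of 0.038 (CDC7) and 0.039 (cdc7-4).

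Gene names came from the locus tags in the array files, matched for 5543 of 5556 loci to a table of yeast gene names of assembly R64, which was used only for names and for which genes are neighbours. No annotation of replication origins was used here, so the fallback fixed beforehand was applied: the peaks of the mean of all 4 arrays took the place of annotated origins and are called Cdc45 regions. For peaks, the mean of probes within 500 bp of each probe (at least 2 probes) was compared with the mirrored negative tail, and the threshold was the lowest value at which that tail held at most 5% as many probes as the positive tail. Probes above it were joined within 1 kb, mitochondrial probes were left out, and the threshold for the mean of 4 arrays was 0.332. The value of a region is the mean of probes within 500 bp of its summit. A region was called low in input when a probe in that window had a mean centred input under -3 on the log2 scale (an eighth of the median), a class defined after seeing the data. Listed origins were placed from general knowledge of their neighbouring genes, before their values were examined, and their value is the mean of probes between those genes (for ARS605 the probes of MSH4). Centromere intervals are the probes between the last left-arm and the first right-arm ORF, tRNA intervals the probes between the genes flanking a tRNA gene where they span at most 5 kb, and an ORF value is the mean of at least 2 probes inside it. Distances to chromosome ends are from the outermost probe.

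Enrichment of each genotype over 0 and the difference CDC7 minus cdc7-4 were tested two-sided with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 on all 4 arrays with no covariates, for regions, origins, probes, ORFs and input signals, with Benjamini-Hochberg adjustment in each family and a threshold of 0.05. The prior degrees of freedom were infinite for regions, which gives every region with 4 values the same SE, and 6.85 for ORFs, 5.96 for probes and 3.05 for input. Gene and region lists fixed before the data were examined were tested with camera (preset correlation 0.01, and an estimated one) and fry, adjusted over the 14 lists. Array means were compared with exact permutation tests, which cannot go below 0.33 here. The permutation test of early against late origins and Fisher's test of regions near centromeres were not in the design fixed beforehand. Overlap of shared peaks with listed origins was set against 1000 circular shifts. Data were loaded with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.

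The genes and places named were chosen by a rule fixed before the data were examined: every listed origin measured, the 15 regions with the highest CDC7 mean among those enriched with both CDC7 arrays above both cdc7-4 arrays, the 5 enriched regions with the largest cdc7-4 mean, the 10 largest region differences and 5 largest ORF differences in each direction past the threshold, the 3 input probes of lowest p since none passed, the 3 highest members of each ORF list, and the 5 highest shared peaks away from listed origins. FUS1, SEN34, CDC5, the named centromeres, the ATO3-EFT2 intergene and the 3 probes higher in cdc7-4 were named after their values were seen.

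The fits were tested on simulated data with the real means and spreads and 200 changed features. Among 540 regions, 88.1% of log2 changes of 0.25, 94.0% of 0.5 and 100% of 1 were recovered with 6 false calls. Among 5138 ORFs the shares were 94.0%, 98.5% and 100% with 9 false calls, among 40356 probes 14.9%, 62.7% and 92.4% with 5, and among 40356 input probes 1.5%, 37.3% and 86.4% with 4. Of 200 simulated peaks, 98.5% of those of height 0.5 and 100% of the taller ones were called in both simulated arrays, and camera called the 1 shifted list and 0 of 13 others. Simulated spreads were independent between neighbouring probes.

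Alternatives covered the signal, background correction, normalization, centring, dim probes, outlier spots, the authors' values, the replicate number as a block, each array left out in turn, the window, a local background, regions near transcribed genes, the variance model, thresholds, peak settings and the list correlation. Added after seeing the data were regions without low input and a joint fit of regions with ORFs.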

Results

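Binding of the replication factor Cdc45 to chromosomes was measured by chromatin immunoprecipitation on a tiling array (ChIP-chip) in budding yeast of the W303 background. Cdc45, which becomes part of the replicative helicase, carried a 13Myc tag and was precipitated with a Myc antibody from cells held in G1 with the mating pheromone alpha-factor for 3 h at 25 °C. The 2 groups were wild-type CDC7 cells (2 arrays) and cells with the cdc7-4 allele (2 arrays), which alters the catalytic subunit of the Dbf4-dependent kinase (DDK). The design asks whether Cdc45 needs this kinase to reach origins of replication in G1. The kinase activity left in cdc7-4 cells at 25 °C was not measured by these arrays, so signal kept in cdc7-4 need not be independent of the kinase. Each array compared IP DNA with input DNA of the same genotype at 41418 probes of 60 bases, with a median spacing of 267 bp. The median IP signal lay 41.9 to 55.9 times above the SD of the negative-control spots and the median input signal 264 to 335 times above it. Values are log2(IP/input) centred on each array's median, so 0 is the typical probe, and they are given as mean ± SD over the 2 arrays of a genotype. Nothing in the labels says that the 2 arrays of a genotype came from separate cultures, so p-values measure only the spread between these samples. Smoothed profiles correlated at r = 0.964 between the CDC7 arrays and 0.980 between the cdc7-4 arrays across probes, which are not independent replicates, and at 0.929 to 0.944 between genotypes. Coordinates are those of the array files, whose genome build is not given in the sources used here.

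Of the 10 measured origins known to fire early, 5 carried a Cdc45 signal of 1.08 or more in CDC7 cells, and most of it was missing in cdc7-4 cells. ARS607, between ROG3 and PES4 on chromosome 6 (probes from 199033 to 199826), read 2.36 ± 0.10 in CDC7 and 0.49 ± 0.09 in cdc7-4. ARS306, between HBN1 and FRM2 on chromosome 3 (74050 to 74681), read 1.88 ± 0.07 and 0.47 ± 0.07. ARS606, between MIC19 and DCV1 on chromosome 6 (167372 to 167829), read 1.62 ± 0.03 and 0.56 ± 0.09. ARS305, next to APA1 on chromosome 3 (38859 to 39724), read 1.35 ± 0.06 and 0.35 ± 0.24, and ARS307, beside PGS1 (108813 to 109031), read 1.08 ± 0.02 and 0.39 ± 0.11. ARS416, also called ARS1, between TRP1 and GAL3 on chromosome 4, was weaker, at 0.44 ± 0.00 and 0.17 ± 0.02. The adjusted p of the difference, by limma with Benjamini-Hochberg adjustment over the 14 measured origins, was 0.000458 for ARS607 and ARS306, 0.000537 for ARS606, 0.00166 for ARS416, 0.00288 for ARS307 and 0.00782 for ARS305.

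Other members of the early list had little signal in either genotype. ARS315, between TAH1 and TVS1, read -0.02 ± 0.02 in CDC7 and -0.21 ± 0.05 in cdc7-4, a difference that passed the test (adjusted p = 0.0145, limma) at a level not above the array median. ARS310 read 0.19 ± 0.02 and 0.15 ± 0.00, ARS309 0.17 ± 0.06 and 0.12 ± 0.03, and ARS605, averaged over 8 probes of the MSH4 gene that holds it, 0.08 ± 0.00 and 0.06 ± 0.01. These last 3 did not pass (adjusted p = 0.172, 0.271 and 0.269, limma). In all, 7 of the 10 early origins were higher in CDC7, adjusted over the list alone.

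The late-firing or silent origins stayed low in both genotypes. ARS603 read 0.27 ± 0.04 in CDC7 and 0.25 ± 0.01 in cdc7-4, and ARS318, beside the silent mating cassette HMR, 0.27 ± 0.03 and 0.27 ± 0.03. ARS316 read 0.04 ± 0.02 and -0.01 ± 0.01. Of the 4 measured, ARS302, beside the silent cassette HML, passed the test with 0.11 ± 0.00 against 0.04 ± 0.01 (adjusted p = 0.0395, limma). The mean of the early list was 0.92 ± 0.01 in CDC7 and 0.25 ± 0.07 in cdc7-4, that of the late list 0.17 ± 0.02 and 0.14 ± 0.01, and 2 arrays against 2 cannot give an exact permutation p below 0.33, which both lists reached. The difference between genotypes averaged 0.66 over early and 0.04 over late origins, and a two-sided exact permutation test over the 1001 ways to draw the late list gave p = 0.0609 (10 against 4 origins). The origins were placed by their neighbouring genes, 4 of the 18 placed ones had fewer than 2 probes, and the 4 remaining members of the lists were not analysed here.

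**Figure D1:**
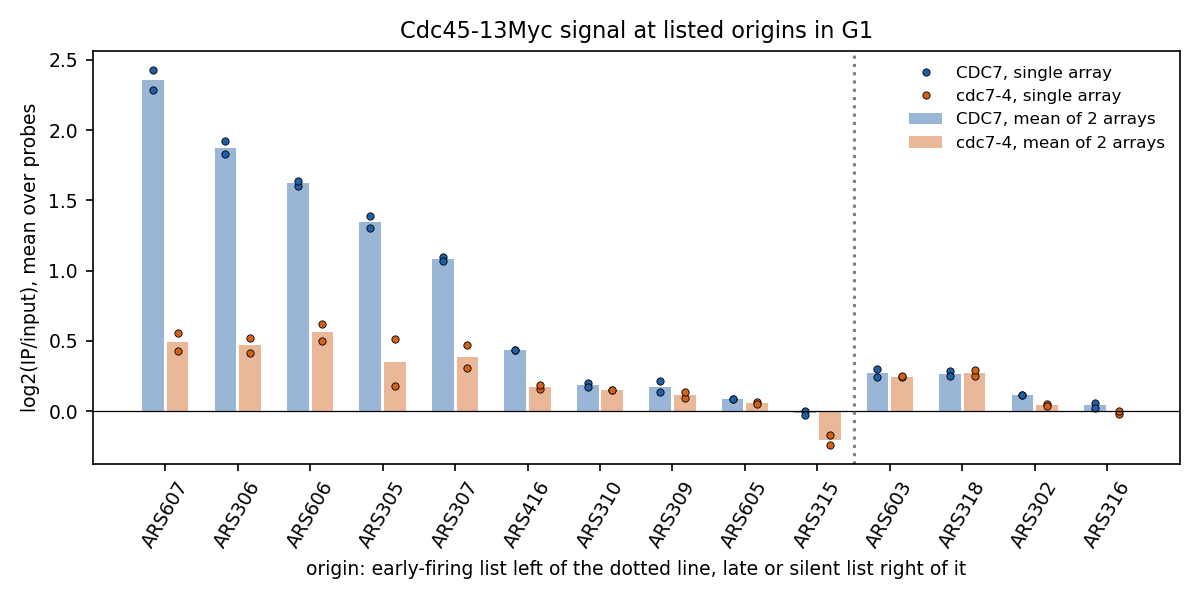
Mean log2(IP/input) over the probes of each listed origin (vertical axis) in CDC7 and cdc7-4 cells; bars are means of 2 arrays and points are single arrays. ARS607, ARS306, ARS606, ARS305 and ARS307 lie between 1.08 and 2.36 in CDC7 and between 0.35 and 0.56 in cdc7-4, while the late or silent origins lie at 0.27 or below in both.

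**Figure D2:**
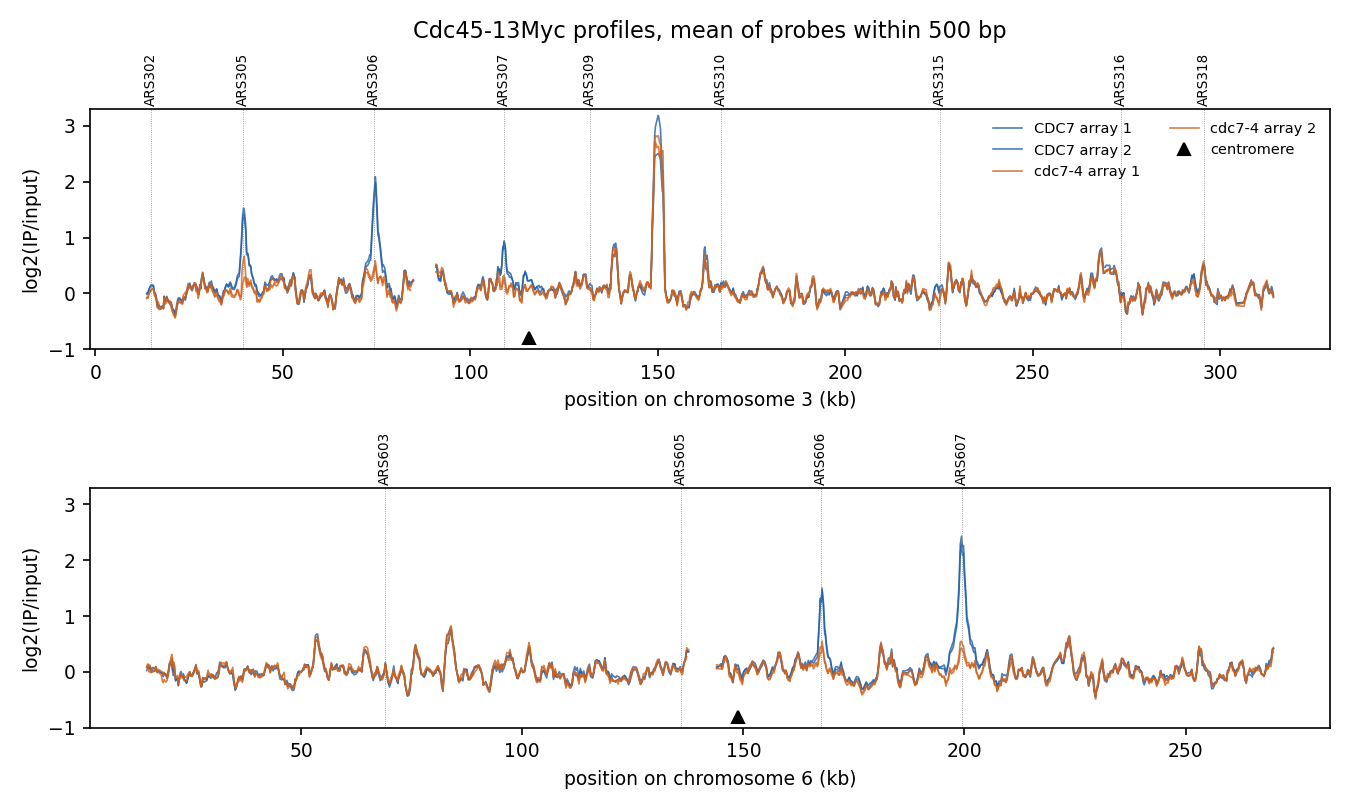
Smoothed log2(IP/input) along chromosomes 3 and 6 (horizontal axis in kb) for the 4 arrays, with the listed origins named above and a triangle at the centromere; lines break where probes are over 2 kb apart. Peaks at ARS305, ARS306, ARS307, ARS606 and ARS607 are tall in the CDC7 arrays and low in the cdc7-4 arrays, and the tallest peak of chromosome 3, near SRD1, has little input DNA and is present in all 4 arrays.

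Across the genome, 34 places with ordinary input DNA had lower Cdc45 signal in cdc7-4, and 31 of them peaked between genes. They came from 547 Cdc45 regions, which are peaks of the mean of all 4 arrays and stand in for annotated origins. Many of the 547 lie near tRNA genes or near transcribed, pheromone-induced or ribosomal protein ORFs. With such regions left out, 311 were enriched in CDC7 and 31 were lower in cdc7-4. At these 34 regions the mean signal was 1.09 ± 0.03 in CDC7 and 0.32 ± 0.06 in cdc7-4, and single regions differed by 0.21 to 1.87. The smallest of these differences, at the ATO3-EFT2 intergene, came from arrays that overlap (0.52 and 0.27 in CDC7, -0.04 and 0.41 in cdc7-4). The PES4 promoter region, which holds ARS607, peaked at 199314 to 199373 on chromosome 6 and was 5.13-fold above the array median in CDC7 and 1.40-fold in cdc7-4. The HBN1 promoter region, which holds ARS306, was 4.10-fold and 1.45-fold above it (chromosome 3, 74622 to 74681). Places not on the origin lists came close. The promoter of FLR1, a multidrug transporter gene, read 2.02 ± 0.05 against 0.81 ± 0.09 (chromosome 2, 255016 to 255075), the site downstream of NOP9 1.94 ± 0.04 against 0.55 ± 0.09 (chromosome 10, 416942 to 417001), and the promoter of ECM10 1.70 ± 0.07 against 0.30 ± 0.05 (chromosome 5, 94001 to 94060).

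The next highest CDC7 values came from the MIC19-DCV1 intergene with ARS606 (1.48 ± 0.03 against 0.51 ± 0.07) and the APA1 promoter with ARS305 (1.43 ± 0.09 against 0.48 ± 0.27). The promoter of ECM15, 0.402 kb from the centromere of chromosome 2 (237775 to 237834), kept most of its signal in cdc7-4, at 1.05 ± 0.13 against 1.40 ± 0.03. YOL024W on chromosome 15 (277466 to 277525, inside the gene) read 1.38 ± 0.07 against 0.23 ± 0.01. VPS8, a vacuolar sorting gene on chromosome 1 (147436 to 147495, inside the gene), read 1.30 ± 0.03 against 0.50 ± 0.08. The promoter of the mitotic exit kinase gene CDC15 (chromosome 1, 176340 to 176399) fell from 1.28 ± 0.06 to 0.08 ± 0.01 and was the one among these 15 regions that was not enriched in cdc7-4 (adjusted p = 0.0921, limma). The GLO1-YML003W intergene on chromosome 13 (263328 to 263387) read 1.26 ± 0.05 against 0.27 ± 0.04, the site downstream of DCG1 on chromosome 9 (411992 to 412051) 1.22 ± 0.04 against 0.15 ± 0.03, the promoter of the hexose transporter gene HXT2 on chromosome 13 (286667 to 286726) 1.17 ± 0.07 against 0.34 ± 0.02, and the site downstream of NCE103, a carbonic anhydrase gene, on chromosome 14 (561085 to 561144) 1.02 ± 0.05 against 0.29 ± 0.06.

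In the limma fit, 35 regions were lower and 0 were higher in cdc7-4 at an adjusted p under 0.05, with 1 region higher at an unadjusted p under 0.05; the additional region, inside LYS2, lies in DNA with almost no input. The fit gave nearly every region the same SE of 0.063, and when regions were fitted together with ORFs, a choice made after seeing the data, 37 were lower, 33 of them among the 35, and 5 were higher, and the ATO3-EFT2 intergene lost its call. Both CDC7 arrays exceeded both cdc7-4 arrays in 74 regions and lay below both in 111, where chance gives 16.7% each way. Outside the called regions the differences were small, from -0.17 to 0.18 with a median of -0.015. Quantile normalization, which forces equal distributions, turned the split to 37 lower and 40 higher regions and ended the call at ECM15. All 547 regions were enriched over the array median in CDC7 and 544 in cdc7-4, which follows in part from choosing them on the same arrays. These counts include regions near transcribed genes and with little input DNA, so they are not counts of origins. Of the 34 regions, 31 remained enriched in cdc7-4. The mean over all regions was 0.54 ± 0.01 in CDC7 and 0.50 ± 0.04 in cdc7-4 (exact permutation p = 0.33, the smallest possible), and the difference of 0.04 was 0.01 without cdc7-4 replicate 1 and turned to -0.004 with quantile normalization.

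**Figure D3:**
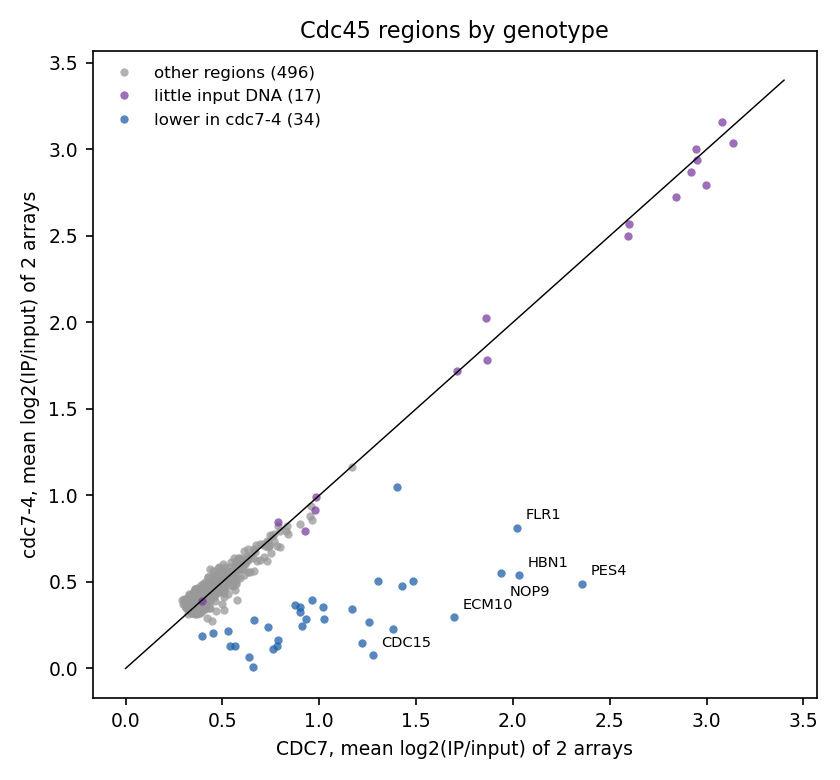
Mean log2(IP/input) of each of the 547 Cdc45 regions in CDC7 (horizontal axis) against cdc7-4 (vertical axis), each the mean of 2 arrays; the line marks equal values. The 34 regions called lower in cdc7-4 lie below the line, the 17 regions with little input DNA lie near it, most at high values, and the others form a cloud along it.

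Cdc45 regions close to centromeres were lower in cdc7-4 far more often than the rest. Of 38 regions within 15 kb of a centromere, 15 were lower, against 20 of 509 elsewhere (odds ratio 15.7, Fisher's exact test, two-sided, p = 2.93e-10, over regions that are not independent). They include the ARS307 region beside PGS1, the GLO1-YML003W intergene, VPS8, and sites near the tRNA splicing endonuclease gene SEN34 (0.79 ± 0.07 against 0.17 ± 0.03) and the polo kinase gene CDC5 (0.64 ± 0.04 against 0.07 ± 0.03). Regions near a centromere averaged 0.66 ± 0.02 in CDC7 and 0.41 ± 0.05 in cdc7-4. The centromere intervals averaged 0.32 ± 0.02 and 0.17 ± 0.01, all 16 were higher in CDC7, and 15 passed when adjusted over the list alone. CEN13 differed by 0.48 and CEN2 by 0.31, while CEN14 differed by 0.01. The called CDC5 and ECM15 regions peaked 0.43 and 0.402 kb from the centromeres of chromosomes 13 and 2. The intervals are therefore not separate evidence from the called regions. With camera at its preset correlation the adjusted p was 5.85e-26 for regions near a centromere, 7.53e-17 for centromeres and 1.86e-18 for early origins. With an estimated correlation these calls were lost (adjusted p = 0.555, 0.240 and 0.246), and fry, which tests a list by itself, gave adjusted p = 0.0886, 0.0299 and 0.0299. In the list of late origins camera gave adjusted p = 0.0982, for all regions 0.986 and for the 489 other regions 0.242, of which 20 were lower in cdc7-4. None of the 20 regions within 20 kb of a chromosome end was called (camera adjusted p = 0.992). Camera called this list with either CDC7 array left out, but in opposite directions of the list mean. CDC7 array 1 (1.15) lay above the cdc7-4 mean of 1.08 and CDC7 array 2 (1.01) below it. Camera also called the late origins without CDC7 replicate 2 (adjusted p = 0.00987). All regions were called with normexp (camera adjusted p = 2.4e-06), with quantile normalization (4.05e-06) and with mode centring (0.00244). The other regions were called with normexp (2.37e-09) and with quantile normalization (2.5e-10). The direction of these calls is not given here. In the main setting, where neither list was called, camera placed both lower in CDC7. These calls can therefore not be read as loss in cdc7-4. Both lists were also called with either cdc7-4 array left out, but the medians of these arrays lay on either side of CDC7. The mean of all regions was lower in both cdc7-4 arrays (0.476 and 0.529) than in the CDC7 arrays (0.534 and 0.547). Medians of all regions were 0.41 and 0.457 in cdc7-4 and 0.424 and 0.445 in CDC7. Those of the other regions were 0.415 and 0.465 in cdc7-4 and 0.416 and 0.438 in CDC7.

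**Figure D4:**
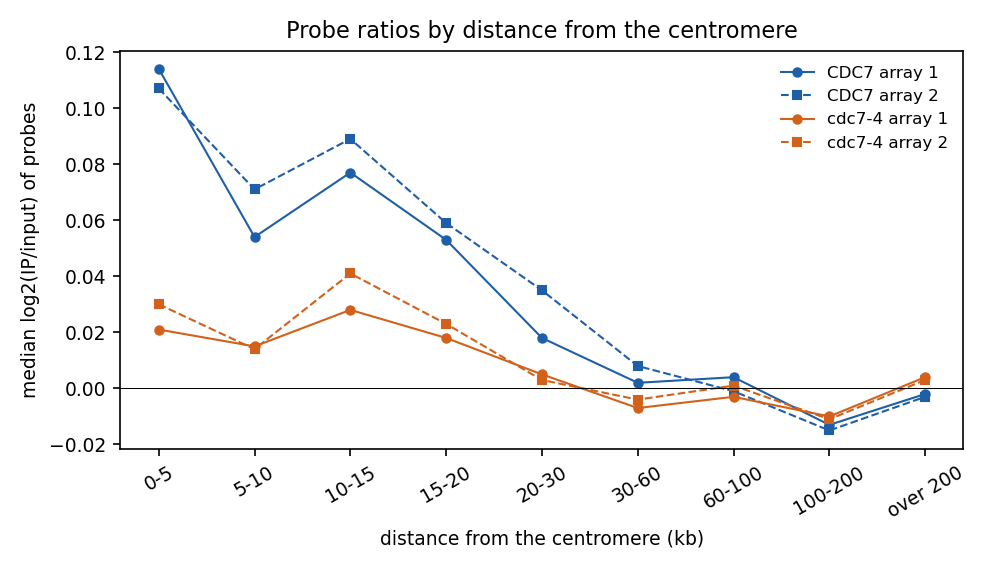
Median log2(IP/input) of all probes by distance from the centromere in kb (horizontal axis) for the 4 arrays. Within 5 kb the medians are 0.11 in both CDC7 arrays and 0.02 and 0.03 in the cdc7-4 arrays, and beyond 60 kb the 4 arrays lie within 0.02 of 0.

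Strongly transcribed genes carried IP signal in both genotypes. The highly transcribed ORFs averaged 0.61 ± 0.11 in CDC7 and 0.61 ± 0.05 in cdc7-4, and 0 of 16 differed, also adjusted over the list alone (camera adjusted p = 0.986). The CDC7 arrays themselves differed here, at 0.53 and 0.69, on either side of the cdc7-4 mean. Camera called the list with either CDC7 array left out, but in opposite directions of the list mean. Without CDC7 replicate 1 the CDC7 value lay above that of cdc7-4, and without CDC7 replicate 2 below it. Among the highly transcribed ORFs the glycolytic genes FBA1 (1.18 ± 0.19 and 1.12 ± 0.15), PDC1 (1.1 ± 0.22 and 0.96 ± 0.19) and GPM1 (0.79 ± 0.12 and 0.78 ± 0.01) were highest. The ribosomal protein ORFs averaged 0.35 ± 0.04 and 0.36 ± 0.03, led by RPL10 (0.81 ± 0.11 and 0.78 ± 0.04), RPP0 (0.76 ± 0.11 and 0.77 ± 0.02) and RPS13 (0.71 ± 0.08 and 0.70 ± 0.04). The 100 members were drawn by symbol and include RPP1 (0.04 ± 0.03 and 0.06 ± 0.02), which is not a ribosomal protein gene. None of these 100 ORFs passed, while camera placed the list lower in CDC7 (adjusted p = 0.00675, and adjusted p = 0.997 with an estimated correlation), a call that also ended without CDC7 replicate 1 (0.471), without cdc7-4 replicate 2 (0.496), with background-subtracted signals (0.1) and with mode centring (0.152). The tRNA gene intervals averaged 0.30 ± 0.00 and 0.29 ± 0.04, and 7 of 211 were higher in CDC7 when adjusted over the list alone (camera adjusted p = 0.625). Camera called the tRNA list with normexp (adjusted p = 2.47e-05) and with quantile normalization (0.0255). It also called this list with either cdc7-4 array left out, but in opposite directions of the list mean. The CDC7 mean of 0.30 lay above cdc7-4 array 1 (0.26) and below cdc7-4 array 2 (0.32).

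Genes that respond to the pheromone used for the arrest also carried signal in both genotypes, at 0.32 ± 0.04 and 0.33 ± 0.02 over 23 ORFs. STE2, the alpha-factor receptor gene, read 0.63 ± 0.09 and 0.67 ± 0.05, the agglutinin gene AGA1 0.59 ± 0.08 and 0.56 ± 0.03, and BAR1, which encodes the protease that degrades alpha-factor, 0.49 ± 0.05 and 0.54 ± 0.01. The one member that passed was FUS1, the neighbour of the ARS306 region, with 0.52 ± 0.06 against 0.34 ± 0.05 (adjusted p = 0.0245, limma). Camera did not call the list (adjusted p = 0.423). It called the list without CDC7 replicate 2, where the CDC7 mean of 0.29 lay below the cdc7-4 mean of 0.33, opposite in direction to FUS1. The 10 ORFs listed beforehand as silent in glucose lay at -0.04 ± 0.01 and -0.03 ± 0.01, with 0 differing (camera adjusted p = 0.305). The highest members were PHO84 (0.28 ± 0.06 and 0.33 ± 0.01), PHO5 (0.02 ± 0.01 and 0.06 ± 0.01) and MAL31 (0.00 ± 0.01 in both). Expression was not measured here, and PHO84 lay near the mean of the pheromone list, so its place among silent ORFs is doubtful. The 20 loci of DDK and replication genes lay at -0.05 ± 0.01 and -0.05 ± 0.00, with 0 differing (camera adjusted p = 0.986), MCM3, MCM5 and ORC4 being the highest at 0.06, 0.06 and 0.04 over the 4 arrays. Of 154 ORFs near a chromosome end 0 differed (camera adjusted p = 0.423), and the highest, YNR071C, AIF1 and YGL262W at 3.09, 3.01 and 2.73 over the 4 arrays, lie in DNA with almost no input.

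Probe by probe, 383 of 41418 probes were lower in cdc7-4 and 3 were higher (limma, adjusted p under 0.05; 2158 and 1330 at an unadjusted p under 0.05). The split was 423 lower and 69 higher with quantile normalization and 555 and 31 with eBayes trend and robust. Of the 383, 210 (54.8%) lay within 1 kb of the summit of 1 of the 34 regions. Without cdc7-4 replicate 2, 35 probes were higher, and the number without each other array was 16 (CDC7 replicate 1), 1 (CDC7 replicate 2) and 15 (cdc7-4 replicate 1). The 3 higher probes lie inside EST2, inside PDR18, where input is almost absent, and in the promoter of ALK1, where outlier spots left few values.

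Peaks called in each array separately numbered 554 and 523 in CDC7 and 428 and 531 in cdc7-4. Of these, 470 were shared by the CDC7 arrays and 391 by the cdc7-4 arrays, and 114 shared CDC7 peaks overlapped no shared cdc7-4 peak, an overlap that was not tested. With quantile normalization the order turned, to 365 shared peaks in CDC7 and 478 in cdc7-4, and the counts fell to 52 and 11 with normexp and to 181 and 126 with a mirrored tail of 1%. Shared CDC7 peaks came within 1 kb of 7 of the 14 listed origins, where 1000 circular shifts averaged 2.61 (permutation test by shifts, p = 0.00699), and shared cdc7-4 peaks within 1 kb of 4, where shifts averaged 1.53 (permutation test by shifts, p = 0.045). The 5 highest shared peaks away from the listed origins were at YNR071C, AIF1, LYS2, SRD1 and YBR013C in CDC7 and at AIF1, YNR071C, SWH1, PAU11 and SRD1 in cdc7-4. The 5 regions with the largest cdc7-4 mean were at AIF1 (3.16 ± 0.09), YNR071C (3.04 ± 0.13), SWH1, PAU11 and YBR013C, and all of these lie in DNA with under an eighth of the median input. Without such DNA, a choice made after seeing the data, the highest cdc7-4 regions were at FBA1 (1.16), ECM15 (1.05), PDC1 (0.94), YMR013W-A (0.88) and FMP25 (0.86).

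ORFs under or next to the strongest Cdc45 regions differed as well. This is not separate evidence, since some share probes with a region, as YOL024W does. Of 5173 ORFs, 100 were lower in cdc7-4 (limma, adjusted p under 0.05), 75 of them within 5 kb of a called summit. The share of all ORFs that lie so near is not given here. FRM2, beside ARS306, read 1.47 ± 0.09 in CDC7 and 0.26 ± 0.02 in cdc7-4 (adjusted p = 3.92e-07, limma), followed by YOL024W (1.16 ± 0.09 and 0.15 ± 0.01), NOP9 (1.07 ± 0.06 and 0.26 ± 0.05), the allantoin degradation gene DAL2 (0.70 ± 0.05 and -0.11 ± 0.00) and its neighbour DCG1 (0.94 ± 0.00 and 0.19 ± 0.05). The 5 ORFs higher in cdc7-4 differed by far less: FSF1 rose from 0.04 ± 0.02 to 0.16 ± 0.04, GLY1, the threonine aldolase gene, from 0.36 ± 0.01 to 0.46 ± 0.03, HOT13 from -0.08 ± 0.00 to 0.02 ± 0.02, MRPL4 from 0.20 ± 0.01 to 0.30 ± 0.02 and PUP3, a proteasome subunit gene, from -0.11 ± 0.02 to -0.02 ± 0.00. Each of these 5 lost its call under several alternatives, and with the replicate number as a block GLY1, HOT13, MRPL4 and PUP3 did not pass (adjusted p = 0.0554, 0.0604, 0.0591 and 0.0803, limma), which left 1 ORF higher. With eBayes trend and robust 193 ORFs were lower and 56 higher. Without cdc7-4 replicate 1 or 2, 26 and 45 ORFs were higher, and without CDC7 replicate 1, 1 was.

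Input DNA gave no called difference between genotypes: 0 probes passed (limma, adjusted p under 0.05), although 5501 had an unadjusted p under 0.05 where chance gives about 2071. Without cdc7-4 replicate 2, 4076 input probes passed, with 1 cdc7-4 array left, and 33 passed without CDC7 replicate 1. The lowest p-values came from a probe in the ALK1 promoter, where outlier spots left 1 array per genotype, from a probe inside the asparaginase gene ASP3-2 (0.02 in CDC7 and 0.69 in cdc7-4) and from 1 in the SRM1 promoter (-0.43 and -0.02), each with adjusted p = 0.376 (limma).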

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

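Leaving out low-input regions and fitting regions with ORFs were chosen only after the results were seen. Under the alternatives 28 to 42 regions were lower in cdc7-4, with 27 to 35 of them among the 35 of the main setting, and each of the 15 named region differences stayed above 0 wherever it had a value, with 1 call lost (ECM15, 0.05, adjusted p = 0.491, under quantile normalization, and from 6.1e-11 to 0.0337 under the others that gave it a value, which the 250 bp window did not). These 15 regions were chosen with both CDC7 arrays above both cdc7-4 arrays, so the sign on the same 4 arrays was largely fixed by that choice. The sizes of the differences moved, at PES4 from 1.56 to 3.22 and at CDC15 from 0.79 to 2.04. With quantile normalization the split of regions was 37 lower and 40 higher, and shared peaks were more in cdc7-4 (478) than in CDC7 (365). Of the named differences under alternatives, 415 kept their side of the threshold and 44 lost it, all but ECM15 at the 5 ORFs higher in cdc7-4. Of the list tests, 211 kept their side, 8 lost their call and 19 gained one. The cause of a change was not tested unless stated.

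Regions higher in cdc7-4, 0 in the main setting, were 5 with normexp, 2 with loess, 40 with quantile normalization, 4 with the authors' value table, 1 with a 250 bp window, 5 with a local background and 5 when fitted with ORFs; without low-input regions, 37 were lower and 0 higher. Probes higher in cdc7-4, 3 in the main setting, were 7 with background-subtracted signals, 1 with normexp, 8 with loess, 69 with quantile normalization, 8 with mode centring, 1 with probes well above background only, 11 with the authors' table, 31 with eBayes trend and robust, 1 at a threshold of 0.01 and 9 at 0.1. ORFs higher in cdc7-4, 5 in the main setting, were 1, 3, 2, 12 and 3 with background-subtracted signals, normexp, loess, quantile normalization and mode centring, 3 with outlier spots kept, 8 with the authors' table, 56 with eBayes trend and robust, 0 at 0.01 and 12 at 0.1. ORFs lower in cdc7-4 were 193 with eBayes trend and robust, and probes lower in cdc7-4 were 231 with normexp.

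The mean region difference of 0.04 turned to -0.004 with quantile normalization, which equalizes the distributions by construction. The early-origin difference of 0.66 was 1.09 with normexp and 0.57 with quantile normalization, and the late-origin difference of 0.04 was 0.011 with normexp and 0.017 with the authors' table. Shared peaks were 52 (CDC7) and 11 (cdc7-4) with normexp and 181 and 126 with a mirrored tail of 1%. With regions near tRNA genes or listed ORFs left out, 311 and 308 regions were enriched, because fewer were tested. Input probes that differed, 0 in the main setting, were 1 with background-subtracted signals and 761 with mode centring. Lists that differed, 4 in the main setting, were 7 with normexp, 7 with quantile normalization and 0 with an estimated correlation. Within 500 bp of a called summit lay 123 of the called probes, against 210 within 1 kb.

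Leaving out each array in turn, with the lone array assumed to vary like the other genotype, gave 33 to 42 regions lower and 0 to 4 higher, 314 to 387 probes lower and 1 to 35 higher, 67 to 137 ORFs lower and 1 to 45 higher, 0 to 4076 input probes differing, 5 to 8 lists differing, a mean region difference of 0.01 to 0.06, an early-origin difference of 0.61 to 0.71 and a late-origin difference of 0.02 to 0.05. The 4076 input probes came without cdc7-4 replicate 2. The replicate numbers give 2 pairs, and deviations of same-numbered arrays correlated at 0.023 across probes and 0.191 across smoothed values, which does not settle whether the numbers pair the arrays; the main analysis did not pair them. With the replicate block, 35 regions, 377 probes and 92 ORFs were lower in cdc7-4, 0 regions, 4 probes and 1 ORF were higher, and 0 input probes differed. The slide could not be used as a block, since all arrays lie on 1 slide. Near background the ratio has little meaning, and 38.7% of the spots in low-input regions were well above background in both channels.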

Other observations

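The tests of compressed ratios, of tagged protein and of low input were chosen only after the results were seen.

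Around centromeres the higher CDC7 signal was not limited to the called regions. The median difference over all probes, CDC7 minus cdc7-4, was 0.07 within 5 kb of a centromere, 0.05 at 5 to 10 kb, 0.03 at 10 to 15 kb and 15 to 20 kb, 0.01 at 20 to 30 kb and 0.00 at 60 to 100 kb. All probes include those of called regions. With probes within 5 kb of a called summit left out, the first 5 of these medians were smaller, at 0.048, 0.033, 0.024, 0.018 and 0.010. Within 15 kb the median over all probes was above 0 on 16 of 16 chromosomes, from 0.02 on chromosomes 8 and 14 to 0.13 on chromosome 1. Of the 25 ORFs lower in cdc7-4 that lie over 5 kb from a called summit, 10 lie within 15 kb of a centromere.

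The lower ratios at the 34 called regions in cdc7-4 were set against technical explanations. If ratios on the cdc7-4 arrays were compressed, strongly transcribed ORFs would lose a like share. However, 15 of them with all values kept 98.1% of their CDC7 mean, while the called regions kept 29.1%. The gap was wider than the spread of the list between arrays (0.53 and 0.69 in CDC7, 0.64 and 0.57 in cdc7-4). The called regions were chosen as lower in cdc7-4 on these arrays, so their low share was in part fixed by that choice. The early origins, listed beforehand, also fell, from 0.92 ± 0.01 to 0.25 ± 0.07. More input DNA of these places in cdc7-4 is argued against by a median input difference of -0.027 (range -0.09 to 0.22), beside a median ratio difference of 0.65. Less tagged Cdc45 captured at every site in cdc7-4 cannot be told apart from less Cdc45 at origins. The median called region kept 28.9%, and no site bound without the kinase is known here. Single regions kept unlike shares, with 1.28 in CDC7 and 0.08 in cdc7-4 at CDC15 but 1.40 and 1.05 at ECM15, a spread that was not tested. The signal at transcribed ORFs could be background of the IP, and no untagged strain was analysed here. The kinase mutation remains among the open explanations. Array position on the slide coincides with genotype. A position effect that acts on all enriched places alike is argued against by the same 98.1% at transcribed ORFs, beside the fall at the early origins listed beforehand. One limited to the called regions cannot be told apart from genotype by this design.

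The shift around centromeres may reflect more than the flanks of called regions. With probes within 5 kb of a called summit left out, 1194 of 1701 probes within 15 kb of a centromere remained, with a median difference of 0.033 (against 0.051 for all), and it was above 0 on 16 of 16 chromosomes (0.01 to 0.07). Less input DNA around centromeres in CDC7 is argued against as the whole cause by a median input difference of -0.012 beside the ratio difference of 0.051, but it has the sign that cause needs, was above 0 on 1 of 16 chromosomes, and stays open as a part of the 0.033 left away from called summits. Farther out the input difference was -0.009 at 60 to 100 kb, where the ratio difference was 0.00, and -0.005 beyond 200 kb. A candidate explanation that stays open is Cdc45 at origins too weak to be called, which was not tested, and the shift is small beside that at single origins.

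The highest ratios of all arrays lay in DNA that was almost absent from the input. The 17 low-input regions had a median ratio of 2.60 in CDC7 and 2.50 in cdc7-4, among them segments at YNR071C, AIF1, LYS2, SRD1 and YBR013C, with a median lowest input of -8.16 on the log2 scale. Their median IP signal lay at -3.66 relative to the array median, as a ratio of 2 signals near background in place of Cdc45 binding would give. However, 38.7% of the spots in these regions were well above background in both channels, so this may not hold for every spot. No biological explanation was tested, and loss of these segments in the strain is a hypothesis that the input signal alone raises.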
